A study of Mus musculus with 24 samples.

How the data were processed

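RNA from cecal epithelial cells of 24 mice was measured on one-colour Agilent arrays, 1 array per mouse, in 6 groups of 4 mice: germ-free (GF), live BbrY and dead BbrY, at day 3 and day 28. Per the labels, cells were released in a chelating buffer, filtered and lysed, and the RNA was labelled with Cy3. The deposited scanner files hold the processed signal of each spot as intensity, which per the file headers was corrected for background and for trends within the array by Agilent Feature Extraction 9.1.3.1, while the submitters' processing notes name version 9.5. No normalization between arrays was part of those values. The deposited flags per spot (well above background, saturated, outlier, control) are of another kind than intensity (unit other, per the file headers). The series' own value table was checked against the scanner values, and the largest difference was 0, so it gave no separate alternative.

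Control spots were left out, which left 43379 of 45018 spots for 41174 probes. Spots marked as non-uniform or as population outliers were set missing (575 over all arrays, 0.0552%), and 0 spots were saturated. Probes sharing an accession with a RefSeq transcript received its gene symbol (22951 probes, 55.7%). Signals were put on the log2 scale, and each array's 75th percentile over the non-control spots was subtracted. Probes well above background on at least 4 of the 24 arrays were kept, and for each gene the brightest tested probe was used, which gave 20601 features, 11815 with a symbol and 8786 without. A level is given as log2 signal over the array's 75th percentile. Where a gene was not well above background on any array of a group, its fold is given as a lower bound. The number of arrays sets the precision.

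A linear model with a mean per group was fitted to all arrays with limma 3.58.1 (lmFit and eBayes, 18 residual degrees of freedom) in R 4.3.3 with the data.table package (1.17.8). In all 12 contrasts were tested two-sided: the 3 pairs of treatments on each day, the same 3 averaged over both days, GF day 28 against day 3, and the change of the live and of the dead effect between the days. The p values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Genes named in a comparison were the called genes with a symbol whose groups did not overlap and that were well above background on all arrays of the higher group, up to 10 largest rises and 10 largest falls, with up to 4 members per gene list with the smallest p, and any member of a called list. The groups, comparisons, tests, the naming rule, the gene lists and most of the alternatives were set before the data were examined. Clock peak hours and genes expressed from both X chromosomes were listed later. For the clock fits the hours were permuted among genes, which are not independent replicates, so their p values hold no spread between mice.

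The 37 gene lists covered epithelial functions, epithelial cell types and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry, and adjusted over the 37 lists of a comparison. Member counts are given over all genes and adjusted over the list alone. Of 145 list calls over all comparisons 2 held with an estimated correlation, xenobiotic metabolism in live against dead at day 3 and glycolysis and hypoxia in the change of the dead effect. Slide was read from the files and used as a block, fixed for treatments within a day and random for GF day 28 against day 3 (consensus correlation 0.07). Scan day held 1 day of treatment each and could not be used as a block. Replicate numbers were checked for pairing: within a day, arrays of the same number in different groups correlated at a median of 0.09 (24 pairs, from -0.163 to 0.452) after the group means were taken off, against -0.035 for other numbers (72 pairs), and the samples were not treated as pairs. Arrays of different groups on the same slide correlated at a median of 0.163 (30 pairs, 21 over 0.1), against -0.087 for other slides of that day (66 pairs, 8 over 0.1).

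The steps were tested on simulated data with 200 of 20601 genes changed, read out in the comparison of live and GF mice at day 3. Of genes changed 1.5-fold 65.7% were recovered, of those changed 2-fold 83.6% and of those changed 4-fold 90.9%, with 8 false calls. A comparison with no change gave 0 calls in limma. How many false calls arise on real arrays, which correlated within slides, was not tested by this simulation. The alternatives tried were normexp background with an offset of 50, computed from median spot signals because the mean signals set in the plan are not in the files, median scaling, quantile normalization, no filter and a stricter filter, outlier spots kept, the mean over probes, a spread with trend and robust settings, replicate and slide as blocks, only the groups compared, a 2-fold minimum, and leaving out each array. Array weights and leaving out the pair of GF arrays that stood apart were added after the data were seen.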

Results

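Gene expression was measured in cecal epithelial cells of germ-free (GF) mice and of mice that had been GF and were given live or dead BbrY, the name the labels use for the bacterium. Cells were collected 3 or 28 days after the start, and RNA of each mouse was read on a one-colour array, with GF mice as the reference on each day. The 24 arrays formed 6 groups of 4 mice. Between 47.5% and 62.3% of the probes on an array were well above background, the 75th percentile of signal ran from 173 to 304, and any pair of arrays correlated at 0.968 to 0.994. The number of arrays per group limited the precision, and the median standard error of a log2 difference between groups of one day was 0.101. After the filter on dim probes, 20601 features were tested, of which 11815 carried a gene symbol. All mice were labelled female. None of 7 Y-linked probes was well above background on any array, and Xist, the RNA that silences one X chromosome in female cells, was well above background on 23 arrays and not on that of GF day 3 replicate 3. Each of the 6 slides held arrays of all treatments of 1 day, so treatments could be compared within slides, whereas day could not be told apart from slide and scan day.

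The first question was how the epithelium of mice with live bacteria differed from that of GF mice after 3 days (n = 4 mice per group). The tubulin-related genes Tppp3 and Tubb6 rose by log2 values of 2.05 ± 0.22 (SE, adjusted p = 2.67e-05) and 1.90 ± 0.26 (adjusted p = 0.000179). Sprr1a, a small proline-rich protein of cornified envelopes, rose by 1.53 ± 0.19 (adjusted p = 7.84e-05) and Ang4, a secreted antimicrobial ribonuclease, by 1.53 ± 0.25 (adjusted p = 0.000627). Slc40a1, the iron exporter ferroportin, fell by 1.60 ± 0.15 (adjusted p = 1.68e-05), from a level of 3.36 ± 0.18 in GF mice to 1.76 ± 0.09 in live mice (log2 over the array's 75th percentile, SD, n = 4). Ly6m also rose (1.24), and Nat8f5 (-1.72), Nat8 (-1.18), the carbonyl reductase Cbr3 (-1.32), Susd4 (-1.24), the brush-border peptidase Enpep (-1.18) and the interferon-induced Ifit2 (-1.32) fell. Some of the largest changes involved genes dim in 1 of the groups. The chemokine Cxcl1 (1.67), the glycerol channel Aqp3 (1.48) and Speer4d (1.28) rose from a level well above background on 2 of the 4 GF arrays, and Fmo1 (1.32) on 3. Efcab11 was not well above background on any GF array and was at least 1.59-fold higher in live mice (adjusted p = 0.0287, and 0.0619 with slide as a block). The peptidase Mme (-2.09) was well above background on 2 of the 4 live arrays, Rasgrp1 (-1.31) on 3 and the T cell co-receptor gene Cd8b1 (-1.16) on 1.

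Genes of cell division rose together in live mice at day 3. Of 44 measured cell cycle and proliferation genes, 27 rose over all genes and 30 adjusted over the list alone, among them Kif20a (0.53), Cdc20 (0.48) and Ccna2 (0.58). The list's median shift was 0.40 (camera adjusted p = 3.49e-20; adjusted p = 0.496 with an estimated correlation), and it was 0.53, 0.21 and 0.40 within the 3 slides (adjusted p = 5.52e-21 with slide as a block). Markers of T cells and intraepithelial lymphocytes moved the other way in the same mice. Of 32 measured, 18 fell over all genes and 20 adjusted over the list alone, including Cxcr3 (-0.83), Cxcr6 (-0.89) and Ptprc (-0.74). Their median was -0.62 (adjusted p = 3.5e-12; adjusted p = 0.496 with an estimated correlation), and -0.59, -0.98 and -0.32 within the slides (adjusted p = 8.24e-14 with slide as a block).

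Small intestinal enterocyte genes were also lower, with 6 of 23 fallen by either adjustment, such as Mep1b (-0.53) and the bile acid transporter Slc10a2 (-0.52), and a list adjusted p of 0.000171 (adjusted p = 0.66 with an estimated correlation). Within the slides the medians of this list were -0.58, -0.50 and -0.62. Over the 24 arrays its deviations from the group means followed those of Paneth cell genes (Pearson r = 0.854), and whether ileal tissue carried over entered the group difference was not tested. The peptidase genes Enpep and Mme belong to this list, so the same limit holds for them in each comparison where they are named. Paneth cell genes as a list did not pass here (adjusted p = 0.505). Among 26 glutathione and oxidative stress genes, 8 fell and 1 rose over all genes, against 12 and 3 adjusted over the list alone. The fallen members included both subunits of the glutamate-cysteine ligase that starts glutathione synthesis, Gclc (-0.63) and Gclm (-0.54), and the heme-degrading Hmox1 (-1.07 ± 0.17, adjusted p = 0.000601), whereas the peroxiredoxin Prdx6 rose (0.53). This list's adjusted p was 0.00294 (adjusted p = 0.496 with an estimated correlation), with slide medians of -0.07, -0.26 and -0.04. Of 66 mitochondrial respiratory chain genes, 15 rose over all genes and 16 adjusted over the list alone, by small amounts such as 0.29 for Ndufb6 (list adjusted p = 4.04e-07; adjusted p = 0.66 with an estimated correlation). Goblet cell and mucus genes rose in 7 of 26 cases by either adjustment, among them Fut2 (0.67), Clca1 (0.33) and Retnlb (0.81), with an adjusted p of 0.0213 (adjusted p = 0.66 with an estimated correlation). The list of PPAR targets and fatty acid oxidation was split. Pdk4 (0.93) was among 8 that rose, and Ppara itself (-0.49) and Vnn1 (-1.13) were the 2 that fell, of 34 measured (12 and 3 adjusted over the list alone). The adjusted p of that list was 0.0273 (adjusted p = 0.66 with an estimated correlation). Of the colonocyte transporters that carry butyrate, Slc5a8 rose by 0.99 ± 0.10 (adjusted p = 2.1e-05) and Slc16a1 by 0.51.

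Over all genes, 3098 passed the test between live and GF mice at day 3, 1494 higher and 1604 lower, of which 112 changed at least 2-fold, 31 upward and 81 downward. Over all 20601 features the groups did not overlap in 4241, where chance gives 2.86% of genes. With slide as a block 3100 genes passed. The count was 1907 with normexp background, 1801 without the filter on dim probes and 5597 with array weights, which were added after the data were seen. It was 1799 without GF day 3 replicate 2, 1999 without GF day 3 replicate 4 and 2018 without live day 3 replicate 3. Over 14 clock genes the effects followed a cosine of textbook peak hours (r = 0.851, permutation p = 0.001, adjusted p = 0.002). Time of day at killing was not excluded, and its reach into other genes was not tested.

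**Figure D1:**
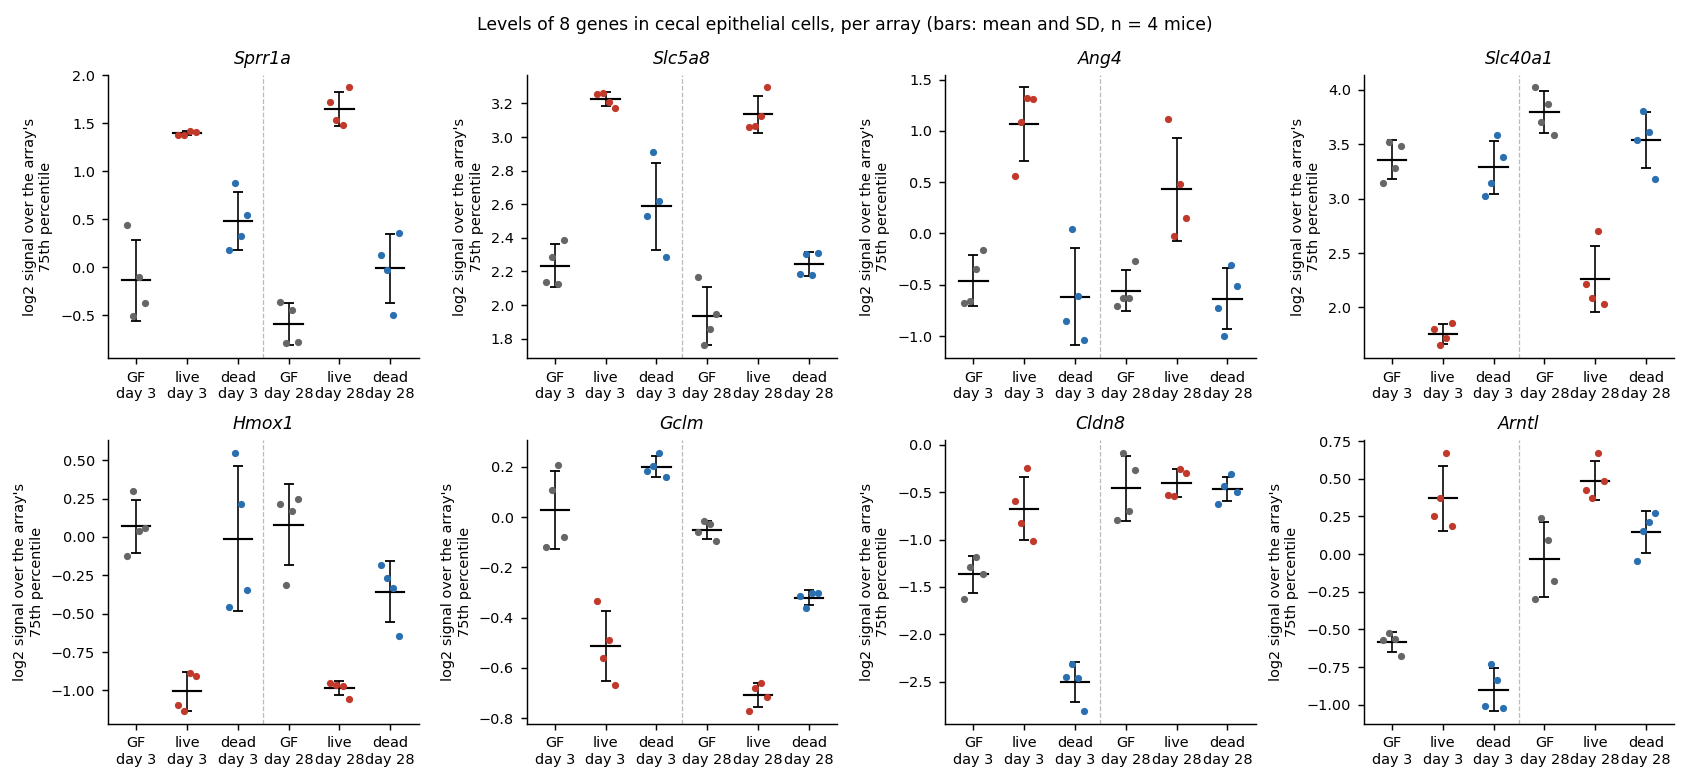
Levels of 8 genes per mouse (y axis: log2 signal over the array's 75th percentile) in GF, live and dead mice at day 3 and day 28, with points for the 4 mice of a group and bars for mean and SD. Slc40a1 lay at 1.76 in live and 3.36 in GF mice at day 3, and at 2.26 and 3.80 at day 28.

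Dead bacteria were compared with GF mice to see what the bacterial material did without live cells (n = 4 mice per group). At day 3 the glucocorticoid-regulated kinase gene Sgk1 rose by 1.07 ± 0.12 (adjusted p = 0.000705), the clock repressor Cry1 by 1.01 ± 0.15 (adjusted p = 0.00124) and the pyruvate dehydrogenase kinase gene Pdk4 by 0.89 ± 0.17 (adjusted p = 0.0038). The effects of 14 clock genes in this comparison followed a cosine of textbook peak hours (r = 0.908, permutation p = 3e-04, adjusted p = 0.00072). Time of day at killing was therefore not excluded, and its reach into other genes was not tested. The lactate transporter Slc16a3 (0.80), Lce3f (1.34), Tex19.1 (0.92), Calcb (0.82), Rtn4r (0.72) and Sptssb (0.71) rose as well, and so did Bmp8b (0.98), which was well above background on 3 of the 4 GF arrays. The tight junction gene Cldn8 fell by 1.14 ± 0.16 (adjusted p = 0.000951), from -1.37 ± 0.19 to -2.51 ± 0.21 (SD, n = 4), and Dgkg (-0.93) and Rarres2 (-1.32) fell. The protease inhibitor Slpi (-1.42), Cav1 (-1.32), Pde4b (-1.11) and Cd8b1 (-0.94) fell to levels well above background on 3 of the 4 dead arrays, Soat2 (-1.30) and Cavin2 (-1.26) on 2. The Wnt agonist Rspo1 (-1.58) was above it on 1 (adjusted p = 0.0361, and 0.0762 with slide as a block).

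Genes of the unfolded protein response rose in dead mice at day 3. Of 25 measured, 12 rose over all genes, and 17 rose and 1 fell adjusted over the list alone. The chaperone gene Hspa5 (0.43), Manf (0.51) and Herpud1 (0.44) were among them. The list's median was 0.20 (adjusted p = 3.28e-09; adjusted p = 0.0644 with an estimated correlation), and 0.25, 0.15 and 0.28 within the slides. Of 33 glycolysis and hypoxia genes, 10 rose and 1 fell over all genes (17 and 1 adjusted over the list alone), including Ldha (0.28), Pgk1 (0.35), Bnip3 (0.51) and Hif1a (0.45). Their adjusted p was 5.33e-08 (adjusted p = 0.0644 with an estimated correlation), with slide medians of 0.15, 0.24 and 0.20. Among 30 genes of mature colonocytes and ion transport, 7 rose over all genes and 14 adjusted over the list alone, such as Krt20 (0.34) and the carbonic anhydrase Car2 (0.28; list adjusted p = 2.17e-05; adjusted p = 0.124 with an estimated correlation).

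Stem cell and crypt genes fell in the same mice, 6 of 18 over all genes and 7 adjusted over the list alone, with Lgr5 at -0.57 ± 0.08 (adjusted p = 0.00104), Ephb3 at -0.59, Cd44 at -0.46 and Sox9 at -0.43 (list adjusted p = 7.5e-05; adjusted p = 0.202 with an estimated correlation). T cell markers were lower too, 13 of 32 over all genes and 17 adjusted over the list alone, such as Cxcr3 (-0.59) and Zap70 (-0.60). Their adjusted p was 3.28e-09 (adjusted p = 0.374 with an estimated correlation), and their slide medians were -0.80, -0.68 and -0.20. Macrophage and dendritic cell markers shifted down with them (median -0.42, adjusted p = 0.00766; adjusted p = 0.374 with an estimated correlation), although 2 of 18 fell by either adjustment, Cd83 (-0.64) and Laptm5 (-0.69), the latter well above background on 3 of the 4 dead arrays. Cholesterol synthesis genes (6 of 28 higher, 7 adjusted over the list alone, such as Fdps at 0.50) had an adjusted p of 0.00138, and 0.535 with an estimated correlation. Androgen, steroid and glucocorticoid response genes (5 of 15 higher over all genes, 5 higher and 1 lower adjusted over the list alone, Tsc22d3 at 0.52) had an adjusted p of 0.0106, and 0.38 with an estimated correlation.

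In all, 1736 genes passed between dead and GF mice at day 3, 938 higher and 798 lower, and 27 changed at least 2-fold. With slide as a block 1513 passed. This comparison depended on its settings. No gene passed limma's test when only its own 8 arrays were fitted, although 3833 had an unadjusted p under 0.05, and the balance of directions was 1244 higher and 589 lower with median scaling and 471 and 637 with quantile normalization. The count was 673 without the filter, and it was 928 without dead day 3 replicate 1, 1122 without dead day 3 replicate 2, and 1101, 959 and 1109 without GF day 3 replicates 1, 2 and 4.

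Live and dead mice were then set against each other at day 3 (n = 4 mice per group). Cldn8 was 1.83 ± 0.16 higher with live bacteria (adjusted p = 2.24e-06), Ang4 1.68 ± 0.25 higher (adjusted p = 0.000195) and the lipid droplet gene Cidea 1.501 ± 0.17 higher (adjusted p = 2.29e-05). Tppp3 (1.36) and Glipr2 (1.27) were also higher. Of genes dim with dead bacteria, Cxcl1 (2.28) and Rspo1 (1.70, adjusted p = 0.0235, and 0.0533 with slide as a block) were well above background on 1 of the 4 dead arrays, Fmo1 (1.44) on 2 and Ceacam12 (1.52) on 3. Nat8f5 (-2.16), the sulfate transporter Slc13a1 (-1.56), Slc40a1 (-1.53), the cystine transporter subunit Slc3a1 (-1.45), Enpep (-1.44), Nat8 (-1.31), Cbr3 (-1.27) and Ifit2 (-1.75) were lower.

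Clock genes stood among the most changed in this comparison. The activator Arntl was 1.27 ± 0.12 higher with live bacteria (adjusted p = 2.24e-06) and Nr1d1 1.23 ± 0.17 higher (adjusted p = 7.97e-05), while Cry1 (-1.18) and Per2 (-1.29) were lower. Of 20 measured, 4 rose and 8 fell over all genes (4 and 9 adjusted over the list alone). The list's median was -0.30, with slide medians of -0.26, -0.14 and -0.36. As a directional list it had an adjusted p of 0.0428 (adjusted p = 0.53 with an estimated correlation), and 0.0686 with slide as a block. The effects of 14 clock genes followed a cosine of textbook peak hours (r = 0.878, permutation p = 2e-04, adjusted p = 0.00072), and time of day at killing was not excluded. The hours were permuted among genes, which are not independent replicates, so this p holds no spread between mice.

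**Figure D2:**
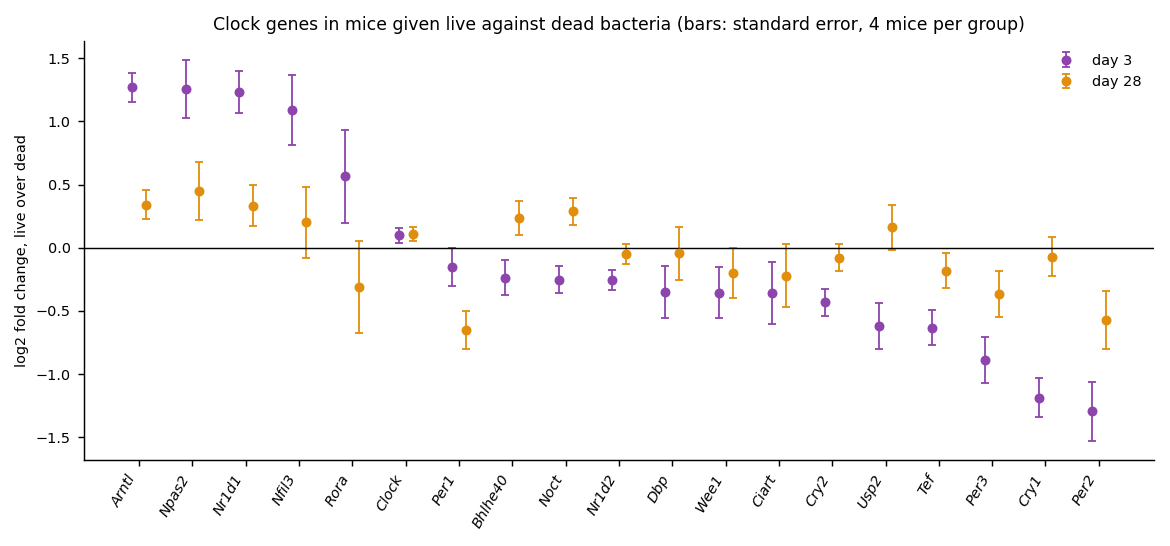
Log2 fold change of live over dead mice (y axis) for 19 of the 20 measured clock genes (x axis), at day 3 and day 28, with bars for the standard error and 4 mice per group. At day 3 Arntl was at 1.27 and Per2 at -1.29, and at day 28 these genes were at 0.34 and -0.57.

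Xenobiotic metabolism genes fell with live relative to dead bacteria at day 3, and this call held with an estimated correlation. Of 44 measured, 15 fell and 3 rose over all genes (17 and 4 adjusted over the list alone), the aldehyde dehydrogenases Aldh1a1 (-0.71) and Aldh1a7 (-0.78) and the cytochrome Cyp2d26 (-0.82) among the lower and the glutathione transferase Gstt1 (1.14, well above background on 3 of the 4 dead arrays) among the higher. The list's adjusted p was 1.32e-07, and 0.0082 with an estimated correlation, and its slide medians were -0.14, -0.28 and -0.17. Of 26 glutathione genes, 11 fell and 1 rose over all genes (12 and 1 adjusted over the list alone), with Gclm at -0.71, Gclc at -0.65 and Txnrd1 at -0.39 (adjusted p = 1.32e-07; adjusted p = 0.101 with an estimated correlation). Cell cycle genes were higher in 18 of 44 cases over all genes and 22 adjusted over the list alone (adjusted p = 1.81e-13; adjusted p = 0.406 with an estimated correlation), and stem cell genes in 6 of 18, or 7 adjusted over the list alone, led by Cd44 (0.66) and Lgr5 (0.53; adjusted p = 0.000173; adjusted p = 0.246 with an estimated correlation). Glycolysis and hypoxia genes were lower in 10 of 33 cases and higher in 2 (12 and 3 adjusted over the list alone), such as Egln3 (-1.05) and Bnip3 (-0.78; adjusted p = 2.18e-05; adjusted p = 0.145 with an estimated correlation).

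Of 30 genes of mature colonocytes, 8 were lower and 2 higher over all genes (13 and 4 adjusted over the list alone), for example Guca2b (-0.77) and the sodium channel subunit Scnn1a (-0.60), while Slc5a8 was higher (0.64; adjusted p = 6.04e-05; adjusted p = 0.16 with an estimated correlation). Small intestinal enterocyte genes fell in 7 of 23 cases, or 9 adjusted over the list alone, with slide medians of -0.76, -0.74 and -0.03 (adjusted p = 5.4e-06; adjusted p = 0.306 with an estimated correlation). Ileal tissue carried over was not tested as a source of this difference either. Paneth cell genes were shifted up at an adjusted p of 0.0145 (adjusted p = 0.502 with an estimated correlation), with Ang4 and Itln1 (0.95) called among 10 measured over all genes and 3 adjusted over the list alone. Their slide medians were -0.29, -0.20 and 1.86, so the shift came from 1 of the 3 slides.

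Between live and dead mice at day 3, 1661 genes passed, 834 higher and 827 lower, with 82 changed at least 2-fold. Median scaling gave 650 higher and 912 lower. The count was 1623 with slide as a block. It was 982 with normexp background, 975 without the filter, 832 when only the 8 arrays compared were fitted, and 992 without live day 3 replicate 3.

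At day 28 the live and GF mice differed in many of the genes already seen at day 3 (n = 4 mice per group). Sprr1a was 2.24 ± 0.19 higher (adjusted p = 6.79e-07), going from -0.59 ± 0.22 in GF to 1.65 ± 0.18 in live mice (SD, n = 4). Cpn1, the catalytic chain of carboxypeptidase N, was 2.43 ± 0.23 higher (adjusted p = 1.21e-06) and the actin-capping Capg 1.79 ± 0.16 higher (adjusted p = 9.09e-07). Ly6m (2.12), Tubb6 (1.98), Tppp3 (1.74) and Tmem252 (1.67) rose too. Aqp3 (2.05), Gcnt1 (1.91) and Speer4d (1.87) rose from levels well above background on 1, 2 and 3 of the 4 GF arrays. The calcium-binding S100g fell by 2.49 ± 0.67 (adjusted p = 0.016), the pantetheinase Vnn1 by 1.89 ± 0.24 (adjusted p = 3.44e-05) and Slc40a1 by 1.54 ± 0.15 (adjusted p = 2.84e-06). Tgfbi (-1.86), Akr1b8 (-1.66) and Susd4 (-1.52) fell, as did genes dim with live bacteria, Ifit2 (-2.33, well above background on 3 of the 4 live arrays), Mme (-2.25, on 1) and Rspo1 (-1.66, on 1). Igfbp7 was not well above background on any live array and was at least 2.32-fold lower there (adjusted p = 0.0221).

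Cell cycle genes were again higher in live mice at day 28, 23 of 44 over all genes and 27 adjusted over the list alone, with 1 lower by either adjustment. Kif20a (0.46), Ccna2 (0.61) and Foxm1 (0.56) rose and Myc fell (-0.41). The median was 0.38 (adjusted p = 1.17e-13; adjusted p = 0.474 with an estimated correlation), with slide medians of 0.36, 0.48 and 0.39. T cell markers were lower in 7 of 32 cases, or 13 adjusted over the list alone, among them Ccl5 (-0.75) and Nkg7 (-0.56), with an adjusted p of 1.36e-05 (adjusted p = 0.474 with an estimated correlation) and slide medians of -0.22, -0.33 and -0.55. Immediate early genes fell in 11 of 27 cases and rose in 1 (16 and 2 adjusted over the list alone), including Nr4a1 (-1.49 ± 0.19, adjusted p = 3.44e-05), Nr4a2 (-0.98) and Dusp1 (-0.70). Their adjusted p was 1.07e-07 (adjusted p = 0.474 with an estimated correlation), and their slide medians were -0.19, -0.42 and -0.32.

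Glutathione genes again held Gclm (-0.66), Gclc (-0.50) and Hmox1 (-1.07) among 5 fallen members, against Prdx6 (0.63) as the 1 risen member, of 26 by either adjustment (adjusted p = 0.00139; adjusted p = 0.474 with an estimated correlation). Goblet cell genes rose in 6 of 26 cases by either adjustment, St6galnac6 by 1.02 and Clca1 by 0.38 (adjusted p = 0.000993; adjusted p = 0.474 with an estimated correlation). PPAR and fatty acid oxidation genes rose in 9 of 34 cases and fell in 2 (17 and 2 adjusted over the list alone), with Cpt1a at 0.41 and Slc27a4 at 0.46 (adjusted p = 0.00237; adjusted p = 0.474 with an estimated correlation). Colonocyte genes rose in 9 of 30 cases and fell in 2 (10 and 3 adjusted over the list alone), with the butyrate transporters Slc5a8 (1.203 ± 0.10, adjusted p = 6.79e-07) and Slc16a1 (0.70), the water channel Aqp8 (0.54) and Clca4a (1.23). That list's adjusted p of 0.0391 became 0.0828 with slide as a block, and it was 0.641 with an estimated correlation. Of 24 enteroendocrine genes 6 rose, or 7 adjusted over the list alone, and 3 fell, and the hormone genes Pyy (1.07), Nts (1.06) and Sct (0.51) and the fatty acid receptor Ffar4 (0.75) were among the risen. Its adjusted p was 0.0372, 0.0566 with slide as a block and 0.641 with an estimated correlation. Interferon response genes fell in 8 of 39 cases, or 9 adjusted over the list alone, such as Ddx58 (-0.91) and Psmb8 (-0.85), and Isg20 rose (0.56; adjusted p = 2.68e-05; adjusted p = 0.534 with an estimated correlation). Their slide medians of -0.33, -1.02 and -0.03 varied widely, and so did their mean level in the GF mice of day 28, from 0.22 to 1.27 relative to all arrays.

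Between live and GF mice at day 28, 2939 genes passed, 1765 higher and 1174 lower, and 155 changed at least 2-fold. With slide as a block 2923 passed. The count was 1943 with normexp background, 1951 without the filter and 1137 when only the 8 arrays compared were fitted. Over 14 clock genes the effects followed a cosine of textbook peak hours (r = 0.681, permutation p = 0.0219, adjusted p = 0.0292). Time of day at killing was not excluded, and its reach into other genes was not tested.

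At day 28 dead bacteria were again compared with GF mice (n = 4 mice per group). Calcb, a calcitonin-related peptide gene, rose by 1.30 ± 0.20 (adjusted p = 0.000872) and the phosphatase gene Dusp10 by 1.27 ± 0.22 (adjusted p = 0.00199). Cd8b1 (0.97), Smim5 (0.97) and Ms4a4b (0.91) also rose. Slc36a4 (1.27) rose from a level well above background on 1 of the 4 GF arrays, and Il20rb (1.27), Lce3f (1.18), S100b (1.03) and Mmrn2 (0.94) from levels above it on 3. The linker histone gene H1f3 fell by 2.02 ± 0.27 (adjusted p = 0.000303), the heat shock gene Hspa1a by 1.80 ± 0.39 (adjusted p = 0.00693) and Thbs4 by 1.26 ± 0.25 (adjusted p = 0.00425). Cacnb1 (-1.10) fell, as did interferon-induced genes, Ifit2 (-1.52), Ifit3 (-1.31), Bst2 (-1.16) and Isg15 (-1.28, adjusted p = 0.0295, and 0.0545 with slide as a block). Apol9b (-1.32) and Phf11a (-1.15) had adjusted p values of 0.0492 and 0.0306, and of 0.0921 and 0.0671 with slide as a block.

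Of 11 gene lists called between dead and GF mice at day 28, 10 were lower and 0 held with an estimated correlation. With quantile normalization 7 lists were called. Of 66 respiratory chain genes 15 fell over all genes and 24 adjusted over the list alone, such as Sdhc (-0.29), Cycs (-0.27) and Ndufb10 (-0.24). The median was -0.14 (adjusted p = 1.13e-12; adjusted p = 0.333 with an estimated correlation), and -0.07, -0.12 and -0.24 within the slides. Glycolysis and hypoxia genes fell in 8 of 33 cases by either adjustment, Egln3 by 0.61, Bnip3 by 0.36 and Ldha by 0.20, the last at 0.009 (upward) with quantile normalization (list adjusted p = 5.28e-05; adjusted p = 0.214 with an estimated correlation). Heat shock genes fell in 7 of 26 cases by either adjustment, Dnajb4 (-0.46) and Hspa8 (-0.44) among them (adjusted p = 3.84e-06; adjusted p = 0.333 with an estimated correlation). Immediate early genes fell in 12 of 27 cases over all genes, with 15 lower and 1 higher adjusted over the list alone, including Nr4a1 (-1.03), Gadd45g (-0.85) and Btg2 (-0.63; adjusted p = 3.91e-08; adjusted p = 0.333 with an estimated correlation).

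Interferon response genes were lower than in GF mice in 10 of 39 cases and in 24 adjusted over the list alone, such as Stat2 (-0.57) and Oas3 (-0.82), with an adjusted p of 1e-10 (adjusted p = 0.443 with an estimated correlation) and slide medians of -0.95, -0.79 and -0.15. The mean level of these genes, relative to all arrays, was -0.28 to 0.07 in dead and 0.22 to 1.27 in GF mice of day 28, against -0.08 to 0.14 in dead mice of day 3. MHC class I genes fell in 6 of 21 cases, or 7 adjusted over the list alone, with B2m at -0.61 (adjusted p = 0.000912; adjusted p = 0.563 with an estimated correlation). Ribosomal protein genes had a median of -0.14 and 2 of 62 called, Rpl7 (-0.21) and Rpl27 (-0.27), and 0 adjusted over the list alone, with 23 at an unadjusted p under 0.05 in limma. The adjusted p of that list was 1.03e-08, and 0.563 with an estimated correlation, and with quantile normalization the list turned upward.

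Between dead and GF mice at day 28, 2269 genes passed, 1390 higher and 879 lower, and 72 changed at least 2-fold. With slide as a block 2044 passed. With quantile normalization 1574 were higher and 569 lower. The count was 1337 with normexp background, 1097 without the filter, 420 when only the 8 arrays compared were fitted, and 1413, 1271 and 1313 without GF day 28 replicate 2, dead day 28 replicate 2 and dead day 28 replicate 3.

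Of the comparisons within a day, live against dead mice at day 28 gave the most genes (n = 4 mice per group). H1f3 was 2.42 ± 0.27 higher with live bacteria (adjusted p = 1.08e-05), Hspa1a 2.09 ± 0.39 higher (adjusted p = 0.000716), Tex19.1 1.59 ± 0.14 higher (adjusted p = 1.36e-06) and Sprr1a 1.66 ± 0.19 higher (adjusted p = 1.36e-05). Cpn1 (1.60) and the cytochrome Cyp4f15 (1.54) were also higher, as were Speer4d (1.77), Fmo1 (1.62), Ttll9 (1.54) and Gcnt1 (1.52), each well above background on 3 of the 4 dead arrays. S100g was 2.71 ± 0.67 lower on the log2 scale (-2.71, adjusted p = 0.00604), and Akr1b8 (-1.43), Slc13a1 (-1.39), Slc40a1 (-1.27) and Plaur (-1.17) were lower. Ndnf was not well above background on any live array and was at least 2.05-fold lower there (adjusted p = 0.00908), and Mmrn2 (-1.25) was well above background on 2 live arrays. The red cell genes Hba-a1 (-1.59), Hbb-bt (-1.45) and Alas2 (-1.42) were lower with live bacteria. The list of erythrocyte and platelet markers, with 2 of 4 members lower over all genes and 3 adjusted over the list alone, had an adjusted p of 0.225.

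Respiratory chain genes made up the broadest shift in this comparison. Of 66 measured, 41 rose over all genes and 57 adjusted over the list alone, for example Uqcrfs1 (0.43), Cycs (0.40) and Ndufb6 (0.30). The median was 0.22 (adjusted p = 3.38e-14; adjusted p = 0.45 with an estimated correlation), and 0.13, 0.25 and 0.24 within the slides. Glycolysis and hypoxia genes rose in 20 of 33 cases, or 21 adjusted over the list alone, with Mxi1 at 0.51, Ldha at 0.37 and Pfkl at 0.50 (adjusted p = 7.91e-08; adjusted p = 0.105 with an estimated correlation), and their slide medians were 0.25, 0.24 and 0.22. PPAR and fatty acid oxidation genes rose in 17 of 34 cases and fell in 2 (20 and 2 adjusted over the list alone), including Cpt1a (0.36), Acadl (0.40) and Plin2 (0.43; adjusted p = 2.16e-05; adjusted p = 0.305 with an estimated correlation). Cell cycle genes were higher in 22 of 44 cases, or 26 adjusted over the list alone, and 1 was lower (adjusted p = 3.69e-09; adjusted p = 0.846 with an estimated correlation). T cell markers were lower in 10 of 32, or 16 adjusted over the list alone, among them Klrd1 (-0.79; adjusted p = 6.71e-05; adjusted p = 0.846 with an estimated correlation).

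**Figure D3:**
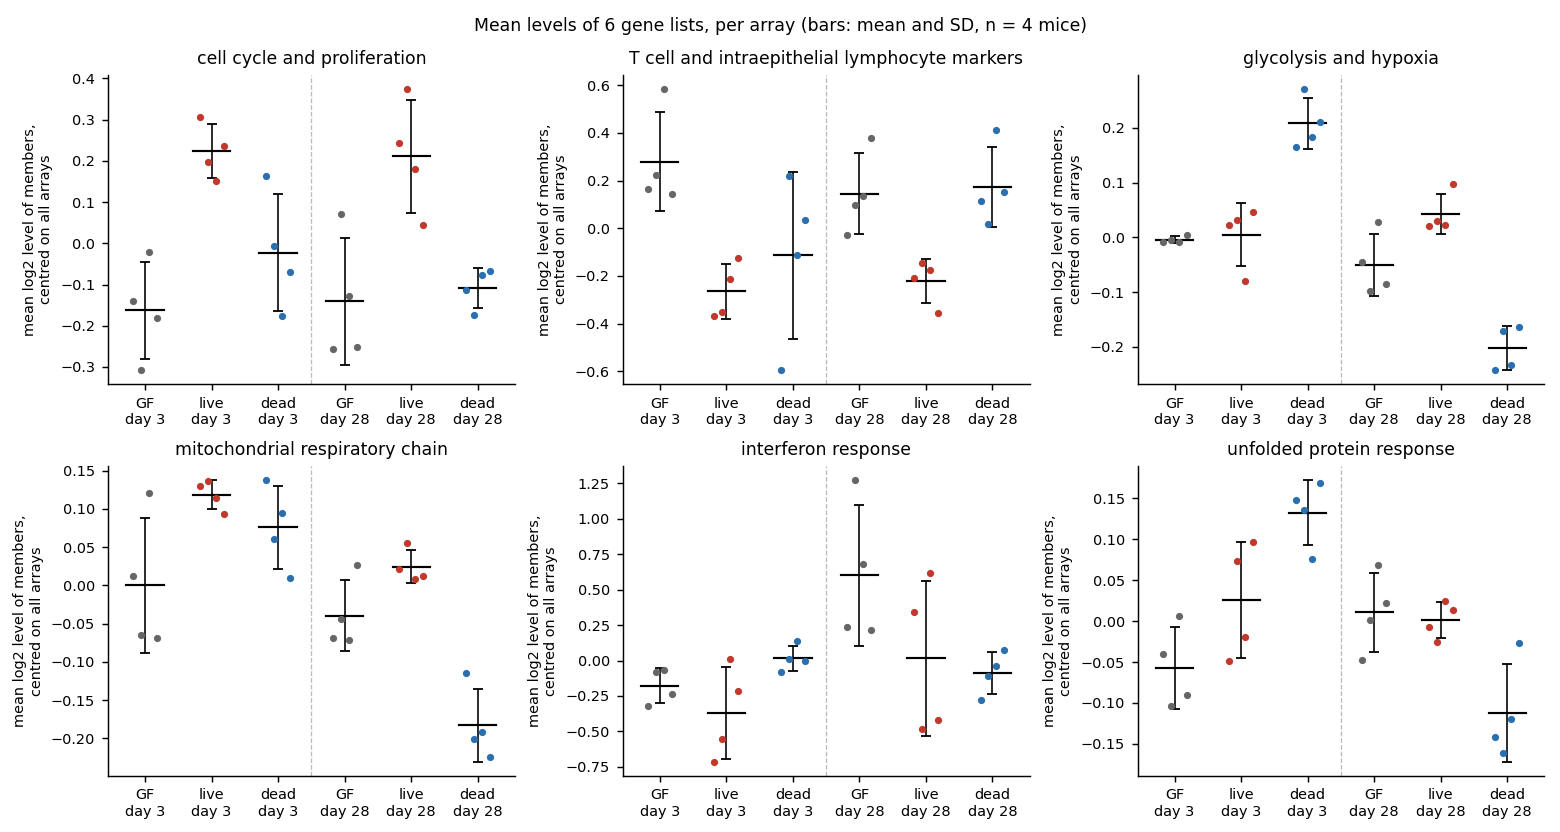
Mean level per mouse of the measured members of 6 gene lists (y axis: log2, centred over all arrays) in GF, live and dead mice at day 3 and day 28, with points for the 4 mice of a group and bars for mean and SD. Interferon response genes reached 1.27 in 1 GF mouse of day 28 and lay at -0.71 in 1 live mouse of day 3.

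Of 20601 genes, 5065 passed between live and dead mice at day 28, 2616 higher and 2449 lower, and 217 changed at least 2-fold. With slide as a block 4964 passed. With quantile normalization 1680 were higher and 2509 lower. The effects of 14 clock genes followed a cosine of textbook peak hours here too (r = 0.939, permutation p = 2e-04, adjusted p = 0.00072). Time of day at killing was not excluded, and its reach into other genes was not tested.

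By gene calls, the effect of live bacteria was more alike on both days than that of dead bacteria. By gene lists the contrast was smaller, with 11 of 37 called for the change of the live effect and 16 for that of the dead effect. Across genes, which are not independent replicates, the live effects of day 3 and day 28 correlated at 0.44, and of 1240 genes called on both days 1229 changed in the same direction. The dead effects correlated at -0.10. Of 340 genes called on both days with dead bacteria, 279 went opposite ways, against 93.9 for independent lists, and 61 the same way. In the test of the difference between the days, 3314 genes passed for dead bacteria, 1721 higher at day 28 and 1593 lower, with 3040 passing with slide as a block. Cry1 (-0.87) and Slc16a3 (-1.15) were lower at day 28 in this test, and Lgr5 (0.68) and Cldn8 (1.13) higher. Over 14 clock genes this change followed a cosine of textbook peak hours (r = 0.724, permutation p = 0.0126, adjusted p = 0.0189), so time of day at killing was not excluded for them. For other genes it was not tested. The glycolysis and hypoxia list was lower at day 28 than at day 3 relative to GF, in 16 of 33 genes over all genes and 22 adjusted over the list alone. Its adjusted p was 2.07e-09, and 0.0415 with an estimated correlation. The balance of the 3314 calls depended on the scaling, with 1685 higher and 797 lower after quantile normalization and 1374 and 1909 after median scaling, and the count was 1867 without the filter. For live bacteria 40 genes passed, 31 higher and 9 lower, with 37 passing with slide as a block and Myc (-0.52) and Aqp8 (0.69) among them. That count was 0 without the filter, 8 with normexp background, 16 with median scaling, 18 with replicate number as a block and 92 with trend and robust spread. It was 283 with array weights, added after the data were seen, and between 0 and 132 when 1 array was left out. It was 9, 69 and 7 without GF day 3 replicates 2, 3 and 4, 26, 9, 5 and 24 without live day 3 replicates 1 to 4, and 132, 12 and 8 without GF day 28 replicates 1, 2 and 4. Without live day 28 replicates 1, 3 and 4 it was 11, 5 and 0, and in the last case 2279 genes had an unadjusted p under 0.05 in limma.

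**Figure D4:**
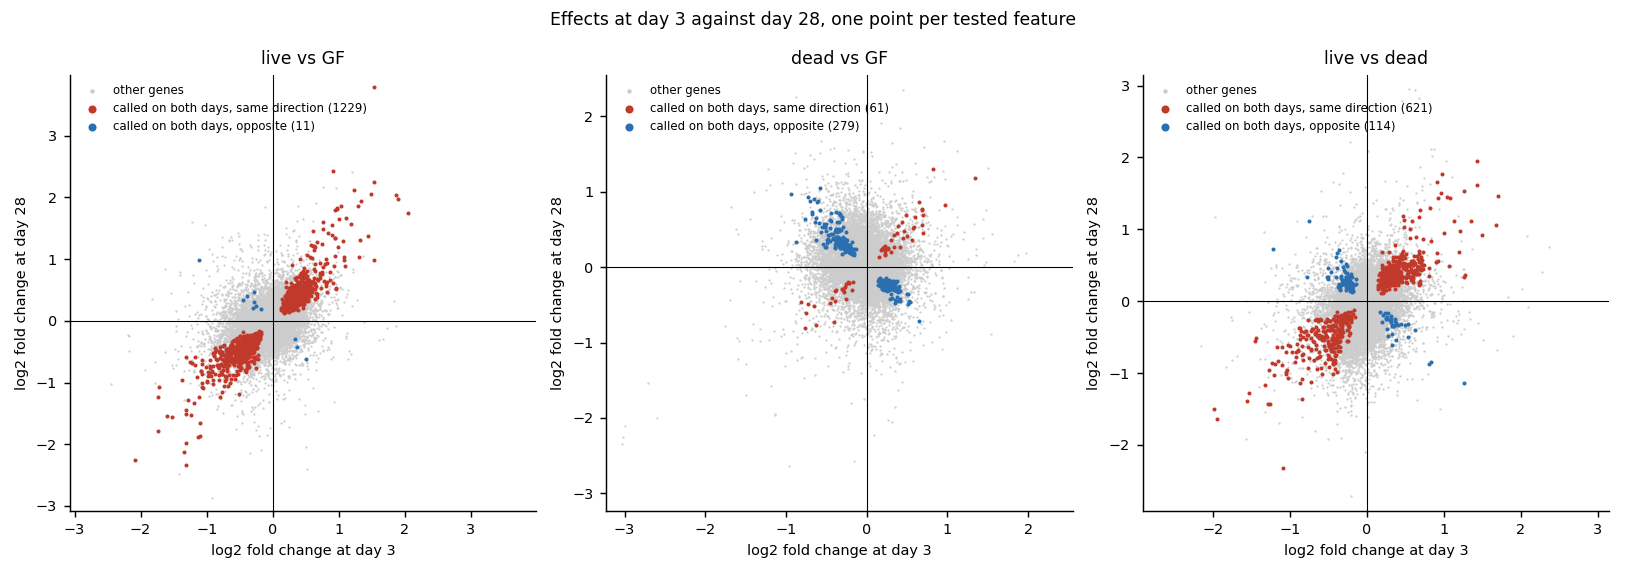
Log2 fold change at day 3 (x axis) and day 28 (y axis) for each tested feature, for live against GF, dead against GF and live against dead mice. Genes called on both days in the same direction numbered 1229, 61 and 621, and those called in opposite directions 11, 279 and 114.

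Averaged over both days (n = 8 mice per group), 5296 genes passed between live and GF mice, 2848 higher and 2448 lower. Sprr1a (1.89 ± 0.14, adjusted p = 4.26e-08), Tubb6 (1.94), Tppp3 (1.89), Ly6m (1.68), Cpn1 (1.67) and Tmem252 (1.39) led the rises, and Slc40a1 (-1.57 ± 0.11, adjusted p = 2.41e-08), Vnn1 (-1.51), Tgfbi (-1.48), Cbr3 (-1.38), Susd4 (-1.38) and Akr1b8 (-1.38) the falls. Cell cycle genes rose in 34 of 44 cases, or 38 adjusted over the list alone, with 1 lower (adjusted p = 3.96e-21; adjusted p = 0.475 with an estimated correlation). With slide as a block 5420 genes passed.

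Dead and GF mice differed over both days in 771 genes, 488 higher and 283 lower, and in 569 with slide as a block. Lce3f (1.26 ± 0.22, adjusted p = 0.00614, well above background on 7 of 8 GF arrays) and Calcb (1.06 ± 0.14, adjusted p = 0.00145) led the rises with Clca4b (0.76) and Pdlim2 (0.63), and Nr4a2 (-0.78), Rasd1 (-0.56) and Sox9 (-0.42) the falls. Immediate early genes fell in 6 of 27 cases and rose in 1, or 14 and 3 adjusted over the list alone (adjusted p = 1.3e-07; adjusted p = 0.418 with an estimated correlation). The count was 267 with normexp background, 221 without the filter, 192 with only the groups compared and 252 without the pair of GF arrays that stood apart, an alternative added after the data were seen. It was 509, 507 and 429 without GF day 3 replicate 1, GF day 3 replicate 3 and GF day 28 replicate 4, and 408 and 386 without dead day 28 replicates 1 and 2. Between live and dead mice 4708 genes passed over both days, 2331 higher and 2377 lower, and 4736 with slide as a block. Cyp4f15 (1.40 ± 0.11, adjusted p = 9.5e-08), Ang4 (1.37) and Cidea (1.21) were higher with live bacteria, and Slc13a1 (-1.48), Slc40a1 (-1.40) and Akr1b8 (-1.35) lower. Respiratory chain genes were higher in 33 of 66 cases, or 42 adjusted over the list alone (adjusted p = 1.01e-10; adjusted p = 0.658 with an estimated correlation). Clock genes followed the cosine of peak hours in all of these averaged comparisons. The values of r were 0.878 for live against GF, 0.749 for dead against GF and 0.925 for live against dead. Time of day at killing was thus not excluded here either.

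Effects of live and dead bacteria were compared across genes within a day. At day 3 they correlated at 0.563, with a covariance of 0.0422, against 0.497 and 0.0224 for simulated unchanged groups that share the GF arrays. When the GF arrays were split so that each effect had its own, r lay between 0.10 and 0.29 over 6 splits. Both effects were called higher in 361 genes and both lower in 347, and 31 genes went opposite ways. At day 28 r was 0.38, the covariance 0.0333 and the simulated values 0.495 and 0.0224, with -0.09 to 0.08 after splitting the GF arrays. There 251 genes were higher and 186 lower in both, and 81 went opposite ways. Both effects of a day were taken against the same GF arrays.

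GF mice themselves differed between the days (n = 4 mice per group), in 4256 genes, 1980 higher at day 28 and 2276 lower. Of 37 gene lists 5 were called, 2 higher and 3 lower at day 28, and 0 held with an estimated correlation. Interferon-induced genes were higher at day 28, 21 of 39 over all genes and 27 adjusted over the list alone, such as Ifit3 (1.51 ± 0.35, adjusted p = 0.00475) and Gbp3 (1.501 ± 0.42, adjusted p = 0.0164), with a list adjusted p of 2e-07 (adjusted p = 0.891 with an estimated correlation). MHC class I genes were higher in 7 of 21 cases, or 10 adjusted over the list alone (adjusted p = 0.00603; adjusted p = 0.891 with an estimated correlation). Vmn1r46 (1.49) was higher, and Ceacam1 (-1.26 ± 0.07, adjusted p = 2.88e-09), Gigyf2 (-1.29), Cpn1 (-1.05) and the red cell genes Hbb-bt (-1.44) and Alas2 (-1.42) were lower. Asap2 (-1.06) was lower too, while its 1 other probe went the opposite way. The days lay on different slides and scan days, so these differences cannot be told apart from those, and with slide as a random block 4033 genes passed, but not Ifit3, Gbp3, Hbb-bt and Alas2 (adjusted p = 0.0787, 0.118, 0.149 and 0.135). The count was 945 when only the 8 GF arrays were fitted.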

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

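The tests of Y-linked probes and of other X-linked genes, and the counts of other splits, were chosen after the result was seen, whereas the test of genes expressed from both X chromosomes was set after the Xist level was seen and before its own result.

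One array stood far from its group in Xist. GF day 3 replicate 3 had a level of -7.35 (log2 over the array's 75th percentile) where the other 3 GF mice of day 3 lay between 1.00 and 1.10 and all 23 other arrays between 0.25 and 1.10. A failed Xist spot alone is argued against by the other 346 X-linked genes only if the array as a whole was not shifted, which was not tested. Their median on this array was 0.103 over its group, outside the -0.04 to 0.02 of the other arrays. The median over genes expressed from both X chromosomes ranked 2 from the lowest of 24, within the others' range, as a failed spot needs. Of these 10 genes, however, 4 were each lowest of 24, so the median alone does not speak for a failed spot. A male or swapped mouse stays open, because 0 of 7 Y-linked probes were above background on this array and on every other, so no array shows that they detect a male. A single X chromosome may explain it and cannot be told apart from other causes, because the median over 10 genes expressed from both X chromosomes was -0.083, within -0.10 to 0.11 on the other arrays, while Kdm6a, Eif2s3x, Kdm5c and Ddx3x were each lowest of 24 (4 genes, 0.417 by chance). The design names no biological difference for this mouse, and none beyond these explanations by sex chromosomes was tested.

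Of 300 groups of 4 arrays looked at for 1 array far from the other 3, 21 had one, where chance gives about 1 in 20 groups, or 15. Among array measures there were 8 in 30 groups (1.5 by chance), among list scores 12 in 222 (11.1 by chance) and among gene levels 1 in 48. The share of probes well above background was 47.5% on dead day 3 replicate 1 against 58.0% to 58.5% in its group. The median correlation with the own group was 0.9883 for GF day 3 replicate 1, 0.9889 for dead day 3 replicate 1, 0.9807 for GF day 28 replicate 4 and 0.992 for dead day 28 replicate 3, the last one above its group. Xist was also apart, upward, in GF day 28 replicate 1 (1.01) and live day 28 replicate 4 (0.73).

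Among list scores, live day 28 replicate 2 was low in cytokines and chemokines (-0.409) and in immediate early genes (-0.335), and GF day 3 replicate 4 was low in immediate early genes (-0.063) and high in androgen, steroid and glucocorticoid response (0.051). Enteroendocrine genes were low in GF day 3 replicate 1 (-0.39), tuft cell genes in live day 3 replicate 1 (-0.122), PPAR and fatty acid oxidation genes in dead day 3 replicate 4 (0.001) and fibroblast, muscle and endothelial markers in live day 3 replicate 2 (-0.199). B cell and plasma cell markers were low in dead day 3 replicate 1 (-0.401) and dead day 28 replicate 2 (-0.227). Macrophage and dendritic cell markers were high in GF day 28 replicate 4 (0.36), glycolysis and hypoxia genes in live day 28 replicate 4 (0.098), and Hmox1 was low in GF day 28 replicate 2 (-0.315).

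The effects differed between the days in the test of the difference itself, in 3314 genes for dead bacteria and 40 for live bacteria. The count of 40 lay between 0 and 132 when 1 array was left out, with 0 (limma, 2279 genes at an unadjusted p under 0.05) without live day 28 replicate 4, 11 and 5 without live day 28 replicates 1 and 3, and 132, 12 and 8 without GF day 28 replicates 1, 2 and 4. It was 9, 69 and 7 without GF day 3 replicates 2, 3 and 4 and 26, 9, 5 and 24 without live day 3 replicates 1 to 4. Myc (-0.52) and Aqp8 (0.69) differed for live bacteria. For dead bacteria, genes named elsewhere that were higher at day 28 relative to GF were Cd8b1 1.91, Mmrn2 1.44, Ms4a4b 1.37, Il20rb 1.34, Pde4b 1.27, S100b 1.24, Cldn8 1.13, Slc36a4 1.12, Klrd1 1.07, Smim5 0.94, Dgkg 0.93, Ephb3 0.77, Laptm5 0.77, Lgr5 0.68, Ptprc 0.66, Cd44 0.60, Cxcr3 0.60, Zap70 0.59, Glipr2 0.57, Arntl 0.50 (log2). Those lower were H1f3 -2.29, Ifit2 -1.96, Gbp3 -1.82, Isg15 -1.69, Thbs4 -1.64, Bst2 -1.40, Oas3 -1.17, Cacnb1 -1.16, Slc16a3 -1.15, Egln3 -1.09, Sptssb -1.04, Sgk1 -0.99, Tsc22d3 -0.98, Tex19.1 -0.96, B2m -0.88, Psmb8 -0.88, Cry1 -0.87, Bnip3 -0.87, Tgfbi -0.84, Pdk4 -0.80, Ddit3 -0.79, Rtn4r -0.77, Manf -0.71, Btg2 -0.68, Herpud1 -0.66, Dnajb9 -0.61, Dnajb4 -0.60, Dusp1 -0.59, Hspa5 -0.57, Plin2 -0.57, Fdps -0.56, Pgk1 -0.52, Hspa8 -0.52, Sdhc -0.48, Ldha -0.48, Car2 -0.45, Cycs -0.45, Gclm -0.44, Prdx6 -0.44, Hif1a -0.43, Ceacam1 -0.37, Aldh1a1 -0.37, Uqcrfs1 -0.35, Mxi1 -0.34, Elovl6 -0.34, Txnrd1 -0.34, Tnfsf13b -0.33, Dgat2 -0.30, Ndufb10 -0.27, Ndufb6 -0.24. Their adjusted p values ran from 0.000173 to 0.0482. Some Sgk1 spots of day 28 were missing.

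For live bacteria the list tests of the difference gave adjusted p values of 1.62e-13 for ribosomal protein and for immediate early genes, 0.000106 for small intestinal enterocyte genes, 0.000196 for heat shock, 0.00188 for interferon response, 0.00997 for the respiratory chain, 0.0313 for cytokines, 0.0398 for the unfolded protein response, 0.04 for colonocyte genes and for androgen, steroid and glucocorticoid response genes, and 0.0416 for T cell markers. Of these 11 lists 3 were higher at day 28 and 8 lower, and 0 of the calls held with an estimated correlation. With slide as a block 7 lists were called, with replicate number as a block 8, with quantile normalization 8 and with fry 1. For dead bacteria the adjusted p values were 7.07e-12 for the respiratory chain, 2.07e-09 for glycolysis and hypoxia, 1.84e-08 for the unfolded protein response, 5.06e-07 for interferon response, 1.28e-06 for heat shock and 8.96e-05 for ribosomal protein genes. Glutathione genes had 0.000163, T cell markers 0.000205, xenobiotic metabolism 0.00201, PPAR and fatty acid oxidation 0.00424, immediate early genes 0.00581, and androgen, steroid and glucocorticoid response genes 0.0129. MHC class I, colonocyte and cholesterol genes had 0.0168 each and stem cell genes 0.033. Of these 16 calls, glycolysis and hypoxia held with an estimated correlation (adjusted p = 0.0415). T cell and stem cell genes were higher at day 28, the other 14 lists lower. With quantile normalization 7 lists were called for the change of the dead effect, so the number of shifted lists depended on the scaling.

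Other splits of the arrays were counted for each comparison. The real split was the 1 of 35 with the most genes for live against GF at day 3 (3098, highest other 4), dead against GF at day 3 (1736, 229), live against dead at day 3 (1661, 1), live against GF at day 28 (2939, 191), dead against GF at day 28 (2269, 9), live against dead at day 28 (5065, 1) and GF day 28 against day 3 (4256, 1403). Each real count was thus reached by a share under 0.05 of the splits, the smallest share that 35 splits allow, without adjustment over comparisons. The splits were made without regard to slide, although arrays on a slide correlated, so chance within slides was not tested. The GF comparison of days is also a split by slide and scan day, so its count cannot be told apart from these. Among 100 drawn splits it was also the 1 largest for live against GF over both days (5296, 2510), live against dead over both days (4708, 554) and the change of the dead effect (3314, 1588). For dead against GF over both days 2 of 100 splits gave at least the real 771, with 1536 as the highest other, and for the change of the live effect 4 of 100 gave at least the real 40, with 1620 as the highest other. For both of these contrasts another split called more genes than the real one. Labels were drawn within each day. A split that mostly swaps the labels of 1 day turns a change between the days into an effect over both days, and the reverse. What the high splits follow was not tested, so counts of drawn splits cannot decide on chance for contrasts that join both days.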

How the results depend on the processing

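Array weights and leaving out GF day 3 replicate 3 and GF day 28 replicate 4 together were chosen after the data were seen. Normexp was planned on mean spot signals, which the files do not hold, and was run on median signals instead. The other alternatives were planned. Over all alternatives 237 counts stayed within 1.5 times their main value and 74 moved beyond it. Of the correlations of live and dead effects, 13 moved beyond their spread and 19 did not. That spread was the SD of the values with 1 array left out, which are themselves among those counted. The split of 13 and 19 is therefore no independent measure of stability. For named genes, with a value per gene and alternative, 5826 values kept direction and side of the threshold, 320 lost the call, 2 gained it and 1 turned. Counted per gene and comparison, 177 of 281 kept both under every alternative. With only the groups compared 79 of the 281 lost the call and 1 gained it. For called lists 708 values kept the call, 304 lost it and 3 turned. Except where stated, the cause was not tested. Signal over background limits what can be seen: with no filter more dim probes are tested. Scan day as a block was not run, since each day of treatment had its own.

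With normexp background the counts that moved were 1907 (live against GF day 3), 982 (live against dead day 3), 1943 (live against GF day 28), 1337 (dead against GF day 28), 267 (dead against GF over both days) and 8 (change of the live effect). With no filter they were 1801, 673 (dead against GF day 3), 975, 1951, 1097, 221, 0 (change of the live effect, with 2516 of 34578 at an unadjusted p under 0.05 in limma) and 1867 (change of the dead effect). With only the groups compared they were 0 (dead against GF day 3, with 3833 at an unadjusted p under 0.05), 832, 1137, 420, 192, 945 (GF day 28 against day 3) and 2032. Fewer arrays for the spread do not account for all of this. Live against dead gave 5126 genes at day 28 (5065 with all arrays) and 5308 over both days (4708). Of the counts that moved, only the 832 (live against dead at day 3) came from a comparison without GF mice. The fit to all arrays takes the same spread for every group, and whether GF arrays vary more was not tested. Asking for a 2-fold change left by its construction 112, 27 and 82 genes at day 3, 155, 72 and 217 at day 28, 91, 10 and 71 over both days, 407 for GF day 28 against day 3, and 8 and 225 for the changes of the live and dead effects. Quantile normalization gave 1108 for dead against GF at day 3. With replicate number as a block, dead against GF over both days had 501 genes and the change of the live effect 18. Array weights gave 5597 for live against GF at day 3.

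The change of the live effect had 16 genes with median scaling, 86 with the stricter filter, 92 with trend and robust spread, 283 with array weights and 22 without the pair of GF arrays, against 40, and dead against GF over both days had 252 without that pair. Leaving out 1 array in turn gave 1799 to 3504 (live against GF), 928 to 1878 (dead against GF) and 992 to 1535 (live against dead) at day 3. At day 28 it gave 1271 to 2778 for dead against GF, and it gave 386 to 861 for dead against GF over both days and 0 to 132 for the change of the live effect. An estimated correlation left 2 of the 145 list calls. The correlation of live and dead effects across genes was 0.605 at day 3 and 0.172 at day 28 with normexp, 0.622 and 0.479 without the pair of GF arrays, and 0.503 to 0.622 and 0.337 to 0.479 with 1 array left out. With quantile normalization ribosomal protein genes in dead vs GF day 28 turned upward (adjusted p = 0.706) and so did these in the change of the dead effect (adjusted p = 0.141), respiratory chain genes turned in the change of the live effect (adjusted p = 0.455), and Ldha in dead against GF at day 28 was at 0.009.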

Other observations

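All tests of explanations here were chosen after the result was seen, except the relation of Paneth cell genes to the share of probes well above background.

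Some gene groups moved beside those already described. At day 3, tight junction and barrier genes were higher in dead than in GF mice in 6 of 24 cases and lower in 1 (9 and 1 adjusted over the list alone), with Cdh17 at 0.30 and Dsc2 at 0.37 against Cldn8 at -1.14 (adjusted p = 0.00195; adjusted p = 0.175 with an estimated correlation). Lipogenesis genes were higher there in 6 of 26 cases by either adjustment, such as Elovl6 (0.39) and Dgat2 (0.30; adjusted p = 0.00853; adjusted p = 0.374 with an estimated correlation). Cytokine and chemokine genes fell in live against GF mice at day 28 in 4 of 24 cases, or 5 adjusted over the list alone, Tnfsf13b by 0.62 among them (adjusted p = 0.00517; adjusted p = 0.474 with an estimated correlation). Unfolded protein response genes fell in dead against GF mice at day 28 in 3 of 25 cases by either adjustment, with Dnajb9 at -0.42 and Ddit3 at -0.73 (adjusted p = 0.00378; adjusted p = 0.349 with an estimated correlation).

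Antimicrobial and microbe-induced genes as a list did not pass in live against GF mice. At day 3, 5 of 24 were higher and 2 lower by either adjustment (adjusted p = 0.159), and at day 28 it was 6 and 2 over all genes and 6 and 3 adjusted over the list alone (adjusted p = 0.0902). Saa3 fell at day 3 (-0.60). Lists of tuft cell, B cell and plasma cell, neutrophil and mast cell, fibroblast, muscle and endothelial, and pancreatic genes had adjusted p values of 0.719, 0.429, 0.59, 0.862 and 0.841 in live against GF mice at day 3.

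Clock genes differed between live and dead mice, most at day 3. In the fits that follow, hours were permuted among genes, so the p values hold no spread between mice. A cosine of textbook peak hours fitted to the effects of 14 clock genes gave r = 0.878 for live minus dead at day 3 (amplitude 1.61, hour 3.17, permutation p = 2e-04, adjusted 0.00072, 12 comparisons) and r = 0.939 at day 28 (amplitude 0.57, permutation p = 2e-04). Against GF mice the live effects followed it at day 3 (r = 0.851, hour 1.69, permutation p = 0.001, adjusted 0.002) and day 28 (r = 0.681, hour 1.88, permutation p = 0.0219, adjusted 0.0292), and the dead effects at day 3 (r = 0.908, hour 16.9, permutation p = 3e-04, adjusted 0.00072), with r = 0.25 at day 28 (permutation p = 0.697). GF mice of day 28 and day 3 also differed along it (r = 0.666, permutation p = 0.0333, adjusted 0.04), and the change of the dead effect between the days followed it (r = 0.724, permutation p = 0.0126, adjusted 0.0189). Groups killed at different times of day may give such shifts, and live bacteria that act alike on both days may give those of the live mice, since across 20 clock genes, which are not independent replicates, live minus dead effects of both days correlated at 0.645, and neither was excluded.

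Paneth cell genes differed between mice within groups, by -1.35 to 1.09 around the mean among dead mice of day 28. Over the 24 arrays, their deviations from the group means followed those of small intestinal enterocyte genes, with Pearson r = 0.854 (permutation p = 8e-05, adjusted 0.00016) and Spearman rho = 0.852 (permutation p = 4e-05, adjusted 8e-05; 2 relations tested), r = 0.809 without the 2 arrays farthest from the median, 0.943 within day 3 and 0.812 within day 28. Slides of 4 arrays are too few for a value of their own. Signal over background is argued against as the source by r = -0.212 with the share of probes well above background (permutation p = 0.431, adjusted 0.431; rho = -0.097, permutation p = 0.7; r = 0.005 without the 2 farthest, -0.461 within day 3 and -0.049 within day 28). Ileal tissue carried over in varying amounts is a candidate source, and a difference between the mice themselves was not tested.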
